A study of Drosophila melanogaster with 3 samples.

How the data were processed

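Chromatin from formaldehyde-fixed S2 cells was immunoprecipitated with an antibody against Yki in 2 libraries and left without antibody in 1 input library; libraries were made by Nextera tagmentation, size-selected on a gel and sequenced on a HiSeq2000, per the labels' protocols. Groups were taken from the sample titles. The description fields of the same samples name other material, a GAF embryo ChIP for both ChIP libraries and a Yki embryo ChIP for the input; titles, source names, antibody and cell line entries all name Yki or input in S2 cells and were followed. The submitters' processing notes name CASAVA 1.7.0, BWA and Bowtie and the build dm3; which tool did which step, and the peak caller, are not given in the sources used here.

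The authors deposited a list of intervals with chromosome, start and end, and no height, p-value or library. They also deposited a density score, 1 value for each 100 bp, which the file's header describes as smoothed and background-subtracted. That header joins 2 library codes with 1 input code. The codes match no sample label; they were taken to be the 3 libraries of the series, with the ChIP libraries pooled and the input subtracted. None of the 3 libraries has a value of its own. The track held 1685244 samples over 15 sequences, from -659 to 12385, with 37.2% of samples below 0. Starts in the interval list were raised by 1 so that positions are 1-based.

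The scale of the score is not stated, and it was read from the values. Where the density returned to 0 (within 0.001) on both sides of a short bump of at most 17 samples, the sum over the bump had a most frequent value of 4.98 above 0 (1153 of 3007 bumps within 2%) and 1.80 (1.803) below 0 (892 of 1633 bumps within 2%). A further 263 bumps had the size of the first less the second. Only the sums were measured, and other pairs of height and SD would give the same sums. A Gaussian of SD 199 bp with a centre height of 1 gives the first sum. On that choice, 1 ChIP tag was taken as a centre height of 1 and 1 input tag as a depth of 0.36 below 0. Under this reading about 2.76 input tags were set against each ChIP tag. The total number of tags in each library stays unknown. If 1 ChIP tag has a centre height of 1, a height h has a counting variance of at least h divided by the square root of 2. The counting SDs given are that lower bound and rest on the choice of height. Reads without molecular identifiers are not independent molecules. Exact Poisson and binomial intervals cover counting error only, bootstrap intervals cover the spread over peaks or windows, and none covers the spread between libraries.

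Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A sample belonged to a peak if its centre lay inside the interval. The covered length of an arm ran from its first to its last sample. Peaks per Mb have exact Poisson intervals, and the X share was tested with an exact two-sided binomial test. Spacing was compared with 1000 random placements of the midpoints within each arm. Medians of peak minus flank have intervals from 10000 bootstrap resamples of peaks. Heights and windows were compared with permutation tests over peaks or windows (100000 resamples for windows, 20000 for heights). The unit of every test is the peak, region or window, not the library, so p-values describe this pooled profile and not the spread between experiments. In the comparison of chromosome 4, windows of 100 kb with 500 samples or fewer, and the last window of each of the 5 large arms, were left out. The background spread was the median absolute deviation of samples over 1000 bp from any peak.

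Choices of test, alternatives and lists were set before the data were examined, except where said. The rule for named items was, without an annotation of the same build, the 10 highest peaks by density; groups of peaks, the widest peaks, chromosome 4, the regions below 0, the comparison of heights on X, the permutation test over 1 Mb windows and the alternatives named as such were chosen after the values were seen. The planned difference of peak against flanks was to be a ratio and was replaced by a difference, because the score can fall below 0. The planned tests on transcription start sites, annotation classes, motifs and gene lists were not run, since the gene table at hand was of another build and the genome sequence of dm3 was not used here. Tests on peak scores and on agreement between ChIP libraries were not run either, since the list has no scores and the track no values per library. On data simulated on the same arms, the spacing test passed 0.05 in 2 of 40 sets of random midpoints and in 40 of 40 sets with 1 in 10 midpoints moved beside another; the count of regions returned all 200 and 100 planted regions, and the tag weight came back as 0.36 when simulated with 0.36.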

Results

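Binding of Yorkie (Yki) to the genome was measured by chromatin immunoprecipitation and sequencing in S2 cells, an established Drosophila melanogaster line of embryonic origin. Yki is the transcriptional coactivator at the end of the Hippo growth-control pathway; it has no DNA-binding domain of its own and is brought to DNA by partners such as Scalloped. The series held 3 libraries: 2 immunoprecipitated with an antibody against Yki and 1 input library made without antibody. The comparison is therefore of ChIP with input, and the question is where in the genome Yki was bound. The values analysed were 1 list of peaks and 1 density track, each taken to cover both ChIP libraries together, so no value has a replicate error and the agreement of the 2 libraries could not be measured. The number of reads per library is unknown. Density is given in ChIP tag equivalents, where 1 tag was taken to have a height of 1 at its centre, and positions are those of the dm3 build. No gene annotation or genome sequence of that build was used here, so regions are given by position and no peak was assigned to a gene, promoter or sequence motif.

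Yki peaks were spread over all the large chromosome arms and were mostly narrow. The list held 3990 peaks covering 2.37 Mb, of which 3938 (98.7%) lay on arms 2L, 2R, 3L, 3R, 4 and X. A further 12 lay on scaffolds of heterochromatin, 33 on unplaced sequence and 7 on the mitochondrial genome. The median width was 447 bp, with quartiles of 304 and 719 bp and a range from 200 to 5779 bp; for the peaks at or above the median height it was 687 bp. The shortest width, 200 bp, was shared by 72 peaks, and 70 peaks were at least 2 kb wide. The height of a peak, taken as the highest density sampled inside it, had a median of 135 with quartiles of 98.9 and 229.7, and a 95th percentile of 613. A peak of median height carries a counting SD of at least 9.78, before any contribution of the background. Taller peaks were wider (Spearman rho = 0.78 across peaks, which are not independent replicates). Part of this relation may be built in. The density was smoothed, and height is the highest of the samples inside the interval, of which a wider interval holds more.

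The highest peaks lay on arms 3L, 3R, 2R and 2L and on a scaffold of chromosome 3 heterochromatin. On 3L the highest peak, at 616311 to 617300, reached 3173, and the density 2 to 5 kb away on both sides averaged 25.6. On 3R the highest lay at 27538595 to 27539999 and reached 3052, with a flanking mean of -8.04. The next on 3R, at 25597239 to 25602239, reached 2333 over a width of 5001 bp. Peaks at 15993723 to 15994475 on 2R and at 12545099 to 12546743 on 2L reached 1942 and 1877. The other peaks among the 10 highest on these arms were at 16607524 to 16609053 on 3R (1839.7), 14409291 to 14410112 on 2L (1839) and 19070433 to 19075245 on 3L (1755). Counting SDs of these 8 peaks were at least 35.2 to 47.4. The remaining 2 of the 10, which include the highest of all at 12385, sat beside each other on the 3RHet scaffold. The highest peak on X, at 2211350 to 2212012, reached 1232 and was the only X peak among the 48 above 1000 on the 5 large arms.

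The widest peaks were on chromosome 3. The peak at 14747890 to 14753668 on 3L spanned 5779 bp with a mean density of 706. Another 3L peak, at 625582 to 630875, spanned 5294 bp with a mean of 859, and one at 638201 to 642798, spanned 4598 bp with a mean of 528. Only 6 peaks reached 4 kb.

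Peaks stood above their surroundings in most cases. The median of the mean density was 121 inside peaks and 16.1 in the flanks 2 to 5 kb away. The median difference was 107 (95% bootstrap interval 105.04 to 109.6, over 3990 peaks), and 94.1% of peaks lay above their flanks. The other 236 did not. Other listed peaks were not left out of the flanks, so these 236 need not lie at the level of the background. A difference was used because the flanking density was below 0 for 26.2% of peaks, which leaves a ratio without meaning. Because the list and the track cover the same libraries, this describes the list and is no independent test. Peaks took up 1.41% of the sampled positions and held 29.0% of all density above 0. Of 15119 samples above the median peak height, 1460 (9.66%) lay outside the listed peaks, and 214 lay outside when the peaks were widened by 500 bp.

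Peaks were unevenly placed and gathered in groups. The median distance between neighbouring midpoints was 7391 bp, against 20069 bp (central 95% of values 19406 to 20769) when the same number of midpoints was placed at random on each arm. Neighbours less than 5 kb apart made up 43.3% of all pairs, against 16.0% at random (14.98% to 17.01%). With 1000 placements, the two-sided permutation p was 0.002 for both, the smallest they can give. Of the 100 kb windows of the 6 arms, 26.1% held no peak, against 6.38% at random (p = 0.002, permutation). The richest window held 33 peaks, against 11 for the richest window of a median random placement (p = 0.002, permutation). Part of the grouping comes from how intervals were divided: 651 neighbouring pairs were separated by 500 bp or less, and joining them left 3339 regions, with 30.9% of neighbours under 5 kb apart against 13.5% at random (p = 0.002, permutation).

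The groups with most peaks were on 2L, 3L, 2R and 3R. Chaining peaks less than 10 kb apart gave 1748 groups, of which 955 were single peaks and 156 held 5 or more; these 156 took in 34.3% of the peaks on the arms. A stretch of 87.3 kb on 2L, from 12459437 to 12546743, held 38 peaks up to a height of 1877, and its density fell no lower than -69.1. A stretch of 98.5 kb on 3L, from 3374085 to 3472609, held 31 peaks, the highest at 710.02. On 2R, 27 peaks lay between 1588777 and 1645405. On 3R, 26 peaks lay between 25562307 and 25616721, where the density ranged from 2333 down to -498. Stretches with 25 peaks each lay at 470334 to 525157 on 2L and at 603789 to 663860 on 3L. By windows of 1 Mb, the first Mb of 2L had the most peaks, 100 in all, followed by the window from 3 to 4 Mb of 3L with 80. The background spread was also large in the first Mb of 2L, 28.2 against 14.9 over the whole arm. In the 3L window it was 16.2, against 14.7 over that arm. Windows near the centromeres differed: those at 23 to 24 Mb of 3L and 0 to 1 Mb of 2R held 3 and 2 peaks, those at 22 to 23 Mb of 2L and 0 to 1 Mb of 3R held 26 and 22.

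**Figure D1:**
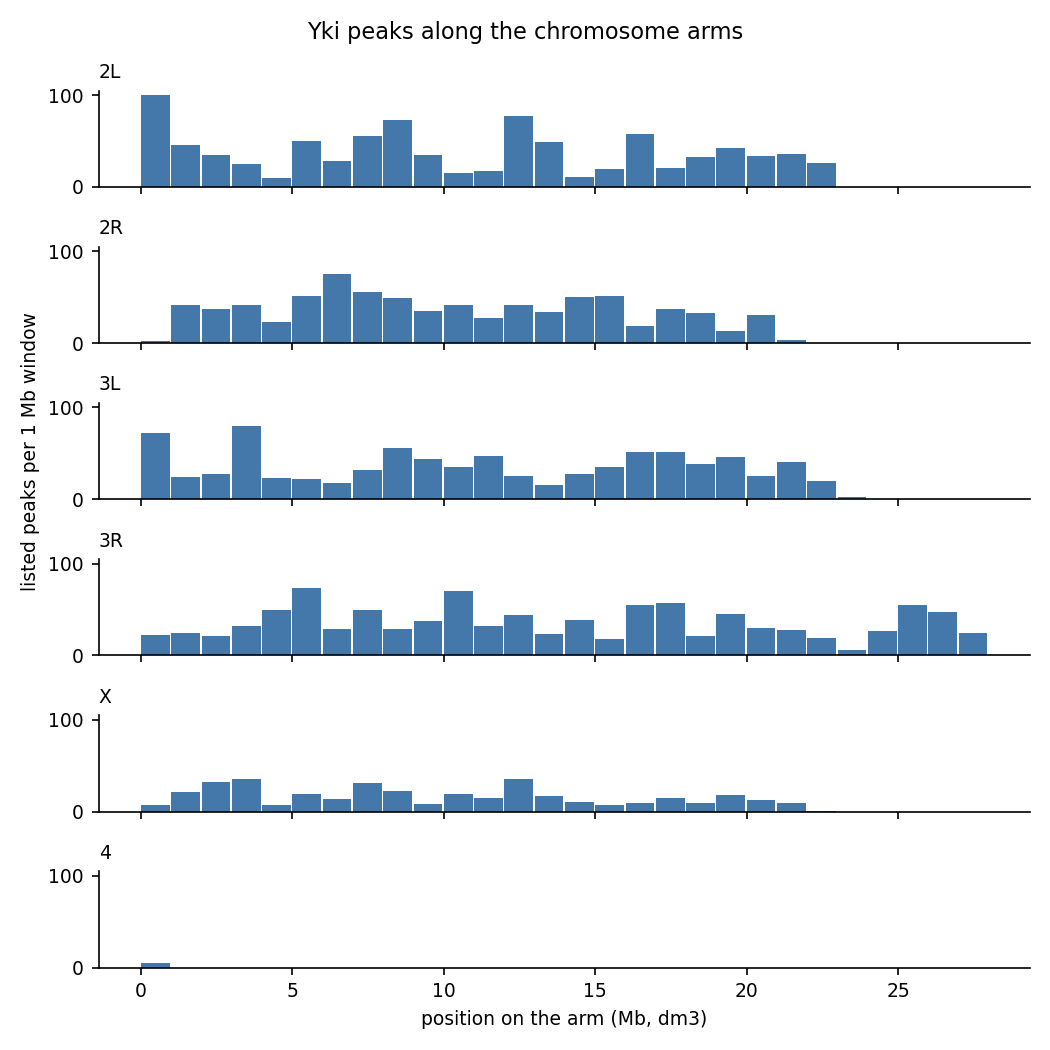
Listed Yki peaks in each 1 Mb window (vertical axis, number of peaks) along arms 2L, 2R, 3L, 3R, X and 4 (horizontal axis, position in Mb, dm3). Bars range up to 100 peaks in the first Mb of 2L, and X windows reach at most 36.

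**Figure D2:**
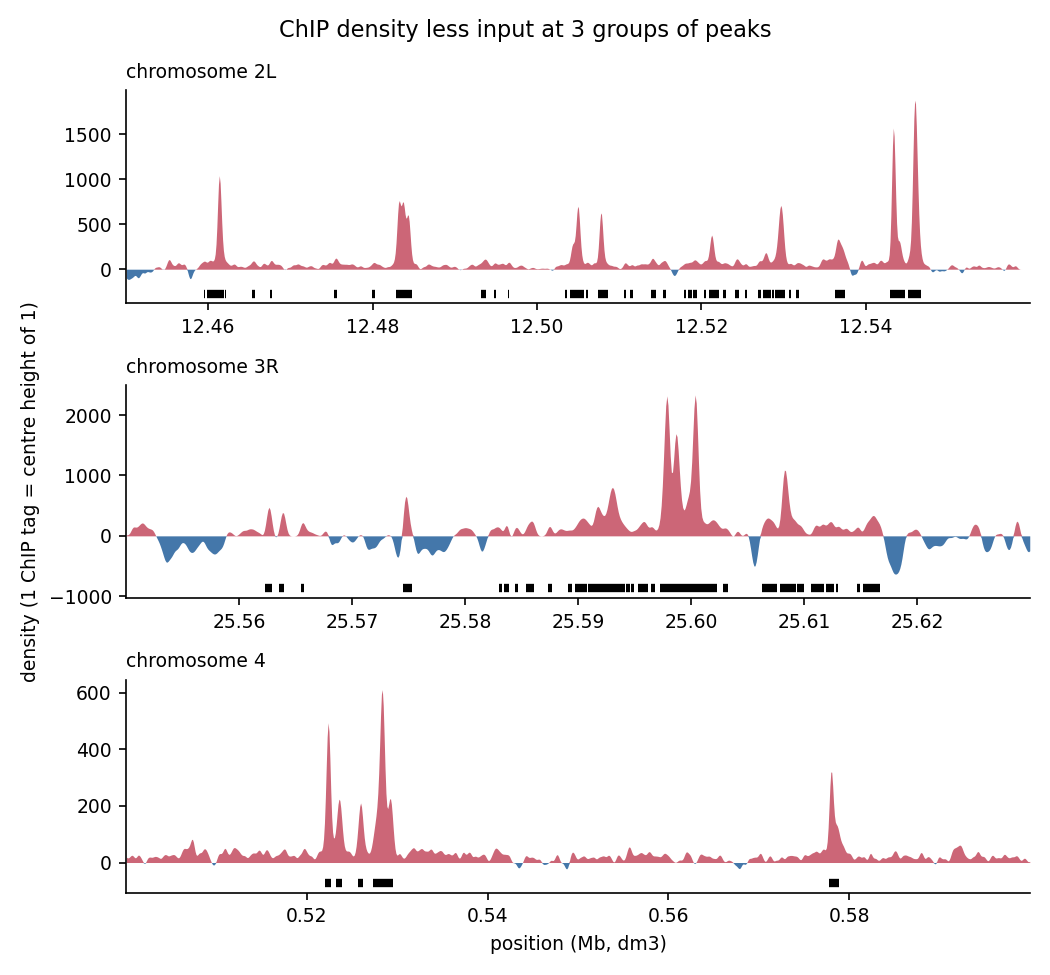
Density of ChIP less input (vertical axes, 1 ChIP tag having a centre height of 1; red above 0, blue below 0) along 3 stretches of 2L, 3R and 4 (horizontal axes, position in Mb, dm3), with listed peaks as black bars. The 2L stretch stays mostly above 0, the 3R stretch holds peaks up to 2333 beside a trough of -633, and the peaks of chromosome 4 reach 611.

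The X chromosome carried fewer than 0.5 times as many peaks per Mb as the autosomes. X held 375 peaks, or 16.7 per Mb (95% exact Poisson interval 15.1 to 18.5). The 4 large autosome arms ran from 35.1 per Mb on 3L (32.8 to 37.5) to 39.0 per Mb on 2L (36.5 to 41.6). X thus held 9.52% of the peaks on the 6 arms (exact binomial interval 8.62% to 10.5%) on 18.6% of their covered length (exact two-sided binomial p = 8.99e-57). The ratio of X to autosome peaks per Mb was 0.46. These intervals cover counting error only and treat grouped peaks as independent, so the comparison was repeated over windows of 1 Mb. X windows held 17 ± 9.38 peaks (SD, 22 windows) and autosome windows 36.6 ± 18.4 (SD, 97 windows), a difference of -19.6 (permutation test, two-sided, p = 2e-05, the smallest the resamples can give). The spread of the density outside peaks was also smaller on X: its median absolute deviation was 10.02, against 14.7 to 16.9 on the 4 autosome arms, a ratio of 0.63.

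Peak heights on X differed from those on autosomes in a way that depended on the lowest height admitted. The median height was 152 on X and 132 on the 4 autosome arms, a difference of 20.8 (permutation test, two-sided, 20000 resamples, p = 0.0005). Among peaks of at least 100 the difference was 1.91 (p = 0.78, permutation), and among peaks at or above the median height of the list it was -27.9 (p = 0.024, permutation), so X was not uniformly higher. The upper end was lower on X, with a 95th percentile of 420.4 against 616 on the autosomes.

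**Figure D3:**
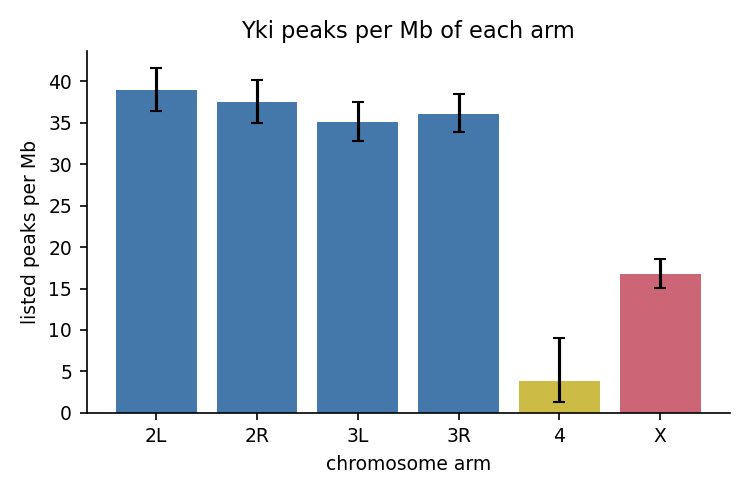
Listed Yki peaks per Mb of covered length (vertical axis) on each chromosome arm (horizontal axis); error bars are 95% exact Poisson intervals, which cover counting error only. The 4 large autosome arms lie between 35.1 and 39.0, X at 16.7 and chromosome 4 at 3.86.

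Chromosome 4, a short and largely heterochromatic autosome, combined few peaks with density above 0 along most of its length. It held 5 peaks, or 3.86 per Mb (exact Poisson interval 1.25 to 9.01). Of these, 4 lay between 522002 and 529504, with heights of 494, 224, 211 and 611, and the fifth lay at 577743 to 578825 with a height of 320.0. The background spread of chromosome 4 was 9.30, against 10.02 on X and 14.7 to 16.9 on the 4 large autosome arms. Whether this smaller spread lowers the number of listed peaks was not tested. The median density of chromosome 4 was 14.8, and 84.4% of its samples were above 0, against medians of 2.55 or less on the 5 large arms. In windows of 100 kb the median was 15.4 over the 13 windows of chromosome 4 with over 500 samples (range 1.60 to 23.9) and 0.26 over the 1187 windows of the other arms, a difference of 15.2 (permutation test over windows, two-sided, p = 2e-05, the smallest the resamples can give). The last window of chromosome 4, with 217 samples, was left out; its median was 0 and 18.4% of its samples were above 0. Neighbouring windows are not independent. Of 1127 contiguous stretches of 13 windows on the other arms, 3 had a median as high; these overlap one another on 2L between 16100 and 17600 kb.

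**Figure D4:**
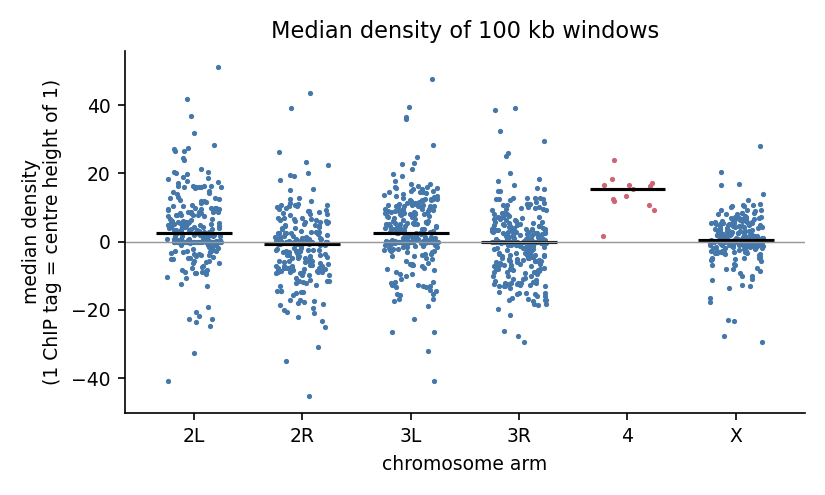
Median density of each 100 kb window (vertical axis, 1 ChIP tag having a centre height of 1) by chromosome arm (horizontal axis); points are windows and black lines the median over windows. The windows of chromosome 4 centre on 15.4, while those of the other arms centre near 0 and range widely on both sides.

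On the 4 large autosome arms, regions below 0 outnumbered regions above 0 at sizes of 50 and 75. The numbers were about equal at 100, and regions below 0 were few at 300 and 500. Sizes under 50 were not counted as regions. Among single samples of any size, more lay above 0 than below on 2L (54.9% against 41.2%) and 3L (54.1% against 42.4%). The reverse held on 2R (46.7% against 49.9%) and 3R (48.0% against 49.9%). Runs of samples at or beyond a given size were counted in both directions. Runs below 0 are no exact mirror of noise above 0, since 1 input tag was taken to weigh 0.36 of a ChIP tag. There were 6297 regions that rose to 50 or more above 0 and 9156 that fell as far below it, a ratio of 0.69. At 75 the numbers were 3804 and 4838, and at 100 they were 2543 and 2663, a ratio of 0.95. At the median peak height the numbers were 1684 and 1061, a ratio of 1.59 (exact binomial interval 1.47 to 1.72). At 200 they were 1062 and 189, at 300 they were 666 and 33, and at 500 they were 296 and 3. On X, regions above and below 0 numbered 416 and 465 at 75, 294 and 136 at 100, and 55 and 6 at 300. Of the 3558 listed peaks on the 4 autosome arms, 27.4% were lower than 100 and 628 (17.7%) reached 300 or more. On chromosome 4 0 regions fell as far as 100 below 0, and 5 rose to 100 above it.

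**Figure D5:**
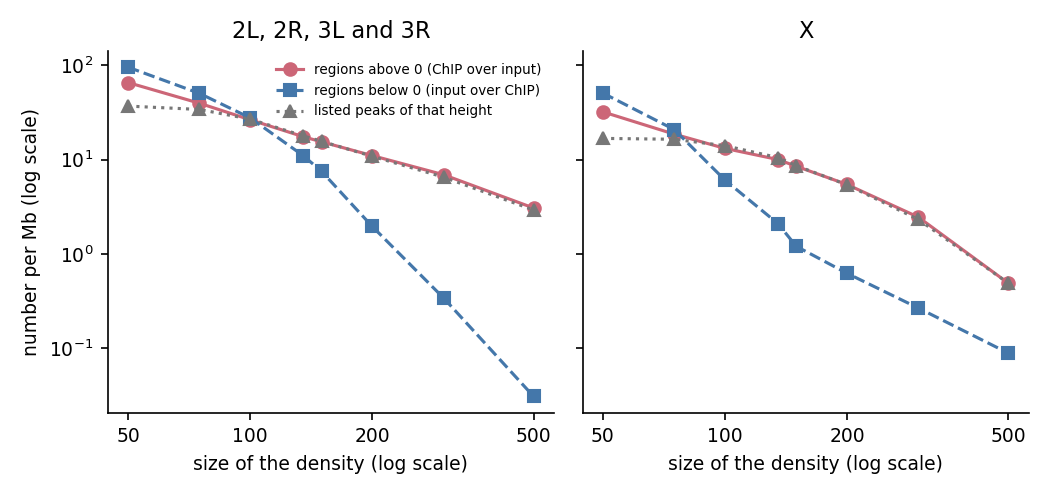
Regions per Mb (vertical axis, log scale) whose density reaches a given size (horizontal axis, log scale) above 0, below 0, and listed peaks of at least that height, for 4 autosome arms (left) and X (right). On the autosome arms the curves above and below 0 cross near 100 and part to 666 against 33 regions at 300.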

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

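These 3 results come from sequences outside the chromosome arms, which entered only the description of the whole list and track, the 10 highest peaks and the difference of peaks from flanks, and they were picked after the data were seen. Input was not given on its own, so each stands on density after subtraction of input. The mitochondrial genome had a mean density of 128 and 7 listed peaks, and none of its samples was below 0. The unplaced sequences U and Uextra held 33 peaks, up to a height of 1336. The highest density of the whole track, 12385, lay on the 3RHet scaffold, where the stretch from 787879 to 791789, with 5 neighbouring peaks and the gaps between them, held 58.1% of the scaffold's density above 0.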

How the results depend on the processing

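Joined peaks, lengths or placements over samples with a density other than 0, placements within 1 Mb windows, the peaks of at least median width, the permutation test over 1 Mb windows, the share of density on arms 2L, 2R, 3L, 3R and X only, and all settings for regions below 0, chromosome 4 and heights on X were chosen after seeing the data. The ratio of peaks per Mb on X to the autosomes stayed below 1 and past 0.05 under all 6 alternatives (0.45 to 0.59), as did the closeness of neighbouring peaks under its alternatives (27.8% to 54.9% of pairs, the last for a distance of 10 kb) and the difference of chromosome 4 (14.2 to 15.4, the first with windows of any coverage). Taking only peaks at or above the median height left 1995 peaks, a median width of 687 bp, a median peak minus flank density of 174, and a difference in height of X from autosomes that turned to -27.9; with peaks of at least 100 that difference was 1.91. Joining peaks across 500 bp gave a median width of 512 bp. Median peak minus flank density was 91.5 with highest values and 114 with flanks 5 to 10 kb away. Widening peaks by 500 bp raised the share of density above 0 inside them to 40.6% and left 214 samples above the median peak height outside. The ratio of regions above to below 0 on the autosome arms was 0.69 at a size of 50 and 0.79 at 75, the reverse of the 1.59 at the median peak height. At 100 it was near 1 (0.95). It was 2.05 at 150, 5.62 at 200, 20.2 at 300 and 98.7 at 500. Widening peaks can only raise the share inside them, and taking peaks at or above the median height fixes their number. The construction fixes neither the ratio of regions above to below 0 nor the sign of the difference in height. For these and the other changes the cause was not tested. Leaving out a library could not be tried. No paired analysis was possible because the files give no value per library. Alternatives on transcription start sites, motifs, gene lists, peak scores, a second list and ChIP replicates were not run. Depth per library is unknown, so no limit of detection can be given.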

Other observations

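Of the tests below, only the correlation of regions above and below 0 across windows was set before its result was seen; the others were chosen after.

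Some of the deepest troughs on the arms lay within a few kb of a peak. Distances in this paragraph run from the lowest sample of a trough to the midpoint of a peak, so the edges lie closer. The lowest region on the arms, at 25617424 to 25618558 on 3R, fell to -633 and was 2.09 kb from the nearest midpoint, with 24 peaks within 50 kb. Troughs at 25521424 to 25522058 on 3R, at 19755776 to 19757110 on X and at 650652 to 650986 on 3L fell to -616, -547 and -520, with 6, 7 and 27 peaks within 50 kb; the last was 0.90 kb from the nearest midpoint and had a peak of 3173 within 50 kb. An X peak of 857, at 19760309 to 19760908, lay beside the X trough. Troughs on 2L at 18664737 to 18664971 (-498) and at 1951337 to 1952471 (-497) were farther, 11.4 and 18.9 kb from the nearest midpoint, with 11 and 3 peaks within 50 kb, the highest at 209 and 110. The lowest value of the whole track, -659, was on Uextra.

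Fewer peaks per Mb were listed on X than on the autosomes. A smaller measured part of X was argued against: per Mb of samples with a density other than 0 the ratio was 0.46 (bootstrap interval over 1 Mb windows 0.35 to 0.58). S2 is a male line. A candidate explanation is a lower overall density on X, as fewer X copies per cell would give, together with 1 height for all arms. A list cut at 1 height of this density was argued against. Listed peaks went down to 40.9. Yet 6297 regions on the autosome arms reached 50, against 3550 listed peaks that high, and on X 716 against 375. At 100 the numbers were closer, 2543 against 2582 and 294 against 314. A lower density on X stays open. The tests below counted regions and not listed peaks, so they cannot tell why fewer X peaks were listed. At the median peak height lowered by the ratio of background spread, X had 0.93 times as many regions per Mb as the autosomes at full height (0.73 to 1.15), against 0.57 (0.42 to 0.76) with no lowering, and at 0.5 times the height it had 1.21 times as many (0.98 to 1.48). The criterion first written for this test, an interval that reaches 1, was met. But the count on X rose at every lower height tried, and at the lowered height X had 362 regions above 0 and 290 below. That criterion was therefore set aside, and a bound on the lower end was added after the values were seen. A second test, also added then, started from a height of 300: the ratio was 0.89 (0.62 to 1.21) with the ratio of spread, 1.23 (0.89 to 1.64) at 0.5 times the height and 0.36 (0.23 to 0.54) with no lowering. With the ratio of spread, the lower ends of 0.73 and 0.62 fell short of the added bound. Neither test therefore meets that bound or excludes a lower density on X. Without that bound both intervals, which reach 1, would have counted for a lower density on X. At 0.5 times the height the lower ends, 0.98 and 0.89, lie above the bound, and there too the count on X rose with the lower height. The intervals also leave room for fewer bound regions on X, and copy number was not measured.

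Density lay above 0 along chromosome 4. A wrong overall scaling of input was argued against, since the highest median outside peaks on the 5 large arms was 0.70, against 14.6 on chromosome 4. The peaks of chromosome 4 do not account for it, since the 12 windows with no peak and over 500 samples had a median of 14.5 (quartiles 11.5 and 16.6), and all 13 with no peak had 13.5 (10.7 and 16.6). A shift shared by sequence next to centromeres was argued against too, since the highest median of the proximal 1 Mb of the 5 large arms was 3.21 against 15.6 on chromosome 4. A difference in base composition or chromatin recovery between ChIP and input, and a broad association of Yki with this chromosome, stay open and untested here.

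At sizes near 100, regions where input exceeded ChIP were as frequent on the autosomes as regions of the opposite sign. The lower peaks of the list thus stand at sizes that regions below 0 also reach. Whether noise above 0 reaches those sizes was not tested, and 1 input tag was taken to weigh 0.36 of a ChIP tag. Counting noise spread without regard to peaks was argued against: the centres of regions at or below minus the median peak height lay a median of 9.98 kb from the nearest peak midpoint, against 17.1 kb at random over the arm (central 95% of values 15.3 to 19.0) and 16.0 kb (14.2 to 17.9) within 1 Mb windows. Local differences in DNA copy or depth may enlarge deviations both ways: across 97 windows of 1 Mb, the numbers of regions above and below 0 were correlated (Spearman rho = 0.30, permutation p = 0.0029; Pearson r = 0.40, permutation p = 0.00025), and after leaving out the 2 windows farthest from the median r was 0.29 (permutation p = 0.0044). Without those 2 windows Spearman rho was 0.26 (permutation p = 0.01). The bootstrap interval of rho over all 97 windows was 0.095 to 0.48. Windows are not independent replicates, and the correlation of regions above and below 0 was the only one of its kind computed. Accessible DNA that is over-represented in the input would give the same relation and stays open.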
